A study of Bos taurus with 16 samples.

How the data were processed

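Gene expression was measured in bovine whole blood on 16 single-colour (Cy3) Agilent oligonucleotide arrays, 4 for each of 4 groups. Per the labels, 10 Holstein cows entered the study, 5 per arm. The treated arm took a commercial oral pack of yeast and of Enterococcus, Lactobacillus and Bacillus bacteria, and the other arm took water, for 60 days. The groups were day 0, probiotic at day 60, untreated at day 60, and probiotic at day 60 with lipopolysaccharide (LPS, a bacterial cell wall component) added to the blood at 100 ng/ml. Blood was kept for 30 min at 37 °C in 5% CO2, and 0.5 µg of RNA with an integrity number above 7 was labelled. RNA of a group's animals was pooled before labelling, so the 4 arrays of a group are repeat hybridisations of 1 pool; on the labels the day 0 pool holds the probiotic cows, and whether it also holds the untreated cows stays open. The p-values therefore measure only the spread between repeat arrays of a pool, taken over all 4 groups, not between cows. Each group lay on a slide of its own, so slide and group cannot be told apart. There were 3 scan days, and only the probiotic and LPS groups shared one, so their comparison lies within 1 scan day; in the other comparisons scan day and group cannot be told apart.

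The authors deposited 1 scanner file per array, made with Agilent Feature Extraction 10.10.1.1, in which the processed signal is an intensity after background subtraction, with no normalization between arrays; the same files hold the median spot and background intensity. On day 0 replicates 2, 3 and 4 and on LPS replicate 4, the software had also multiplied the signal by a factor that changed smoothly over the array (multiplicative detrending). The factor's 5th and 95th percentiles were 0.175 and 17.1 on day 0 replicate 2, 0.166 and 43.8 on replicate 3, 0.503 and 844 on replicate 4, and 0.137 and 15.7 on LPS replicate 4. A deposited table holds 1 log2 value per probe and group. Its differences between groups followed the scanner values for untreated against day 0 (r = 0.998 over 43653 probes) and LPS against probiotic (r = 0.993), but not for probiotic against untreated (r = 0.146) or day 0 (r = 0.635). These correlations are across probes, which are not independent replicates. Its column medians were -0.83 for day 0, 0.26 for probiotic, 0.42 for untreated and 0.01 for LPS. The centring of that table stays unknown, and it was used only as an alternative.

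The processed signal was taken as log2 and each array's 75th percentile over non-control probes was subtracted. The 1417 control spots and the spots the software marked as outliers were left out, spots of 1 probe were averaged, and no spot was saturated. A probe was kept when it was well above background, by the software's own call, on all 4 arrays of at least 1 group. The brightest kept probe stood for a gene, which left 9413 genes, 7001 of them with a gene symbol. Of 43713 probe names, 26903 were given their gene through an accession matched without versions to a bovine RefSeq table, 6525 through a current symbol and 131 through an older one; 1387 kept the symbol of the file and 8767 had none. The array was designed on another bovine assembly than that table, so only names and no positions are given. Among 2135 genes with several kept probes, probes passed in opposite directions in 54 for probiotic against untreated, 112 for probiotic against day 0, 0 for LPS against probiotic and 1 for untreated against day 0.

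Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, in 1 fit of all 16 arrays. The tests were two-sided. A gene's spread was thus taken over all groups, detrended arrays included, even where neither compared group was detrended. Figures were drawn with matplotlib 3.10.9. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 and a fold of at least 2. Errors after ± are standard errors of the fitted difference for genes and SD for arrays. Where the probe of a gene was not well above background on any array of 1 group, the change is given as a bound: the bright group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background. The bound holds for that probe, and other probes of the gene may lie above background. It also holds only under the scaling used, and is no lower limit under another scaling. On the untreated arrays 15.2% of spots were well above background, so the percentile subtracted there lay in dim signal. No fold is given where the probe was dim in both groups or the bound fell under 1. For single genes dim on day 0, detrending had lowered that dim signal, so the bound is taken on the signal before detrending, a choice made after the data were seen; their adjusted p-values remain those of the processed signal. In all, 22 gene lists were tested with camera of limma at a preset correlation of 0.01, adjusted over all lists and comparisons, and their medians were set against 10000 random lists matched on size and signal. They covered inflammatory cytokines and chemokines, NF-kB feedback genes, Toll-like receptor signalling, interferon-stimulated genes, immediate early genes, heat shock proteins, neutrophil markers, monocyte markers, T cell markers, B cell markers, natural killer and cytotoxic genes, erythroid genes, platelet genes, eosinophil and basophil markers, helper T cell cytokines and regulators, MHC class II genes, antimicrobial proteins, Wnt signalling, lipid metabolism, oxidative phosphorylation, ribosomal proteins and cell cycle. The named genes of a comparison were the 8 largest rises and 8 largest falls among genes past the threshold with a symbol, arrays that did not overlap between the groups and signal above background on all of them; up to 3 passing members of each list with the largest change; and always TNF, IL1B, IL6, CXCL8, IL10, TLR2, TLR4 and CD14. The comparisons, lists, thresholds and this rule were chosen before the data were examined. To keep the text short, a choice made after the results, only the first passing member is given for lists that camera did not call. Some genes that meet the rule are not reported here and were not replaced.

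Alternatives were quantile normalization, scaling to the median, cyclic loess, other filters on dim probes, other probe choices, other thresholds, fits of 2 groups alone, averaged arrays, the authors' averages, the replicate number as a block, and leaving out each array. Others were chosen after seeing the data: the signal before detrending (with values under 10 set to 10), normexp background correction with an offset of 50 on the median signal, the 75th percentile over probes well above background on all 16 arrays, leaving out the 4 detrended arrays, and the outer 53 rows at each edge of the array alone. The procedure was tested on simulated data with 200 changed genes added to independent normal noise. The noise had each gene's mean and residual spread from the fit of all 16 arrays, the detrended ones included. A mean-signal version of the normexp correction was not used here.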

Results

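Blood RNA pools of dairy cows were compared on 16 arrays, 4 each for day 0, probiotic at day 60, untreated at day 60, and probiotic at day 60 with LPS. The arrays differed in brightness. Spots well above background made up 32.9 ± 4.70% (SD, n = 4) of spots on the probiotic arrays and 34.4 ± 8.53% on the LPS arrays, against 17.9 ± 6.59% on the day 0 arrays and 15.2 ± 3.06% on the untreated arrays. The range over single arrays ran from 8.26% on day 0 replicate 4 to 42.1% on LPS replicate 3. The 99th percentile of net signal was 13479 ± 3631 scanner units on the probiotic and 1565 ± 336 on the untreated arrays. Arrays of 1 pool had a median Spearman correlation across probes of 0.839 in the probiotic, 0.701 in the day 0, 0.619 in the LPS and 0.485 in the untreated group, and probiotic and untreated arrays one of 0.146; probes are not independent replicates. With 4 arrays per group, the number of arrays limits the precision.

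**Figure D1:**
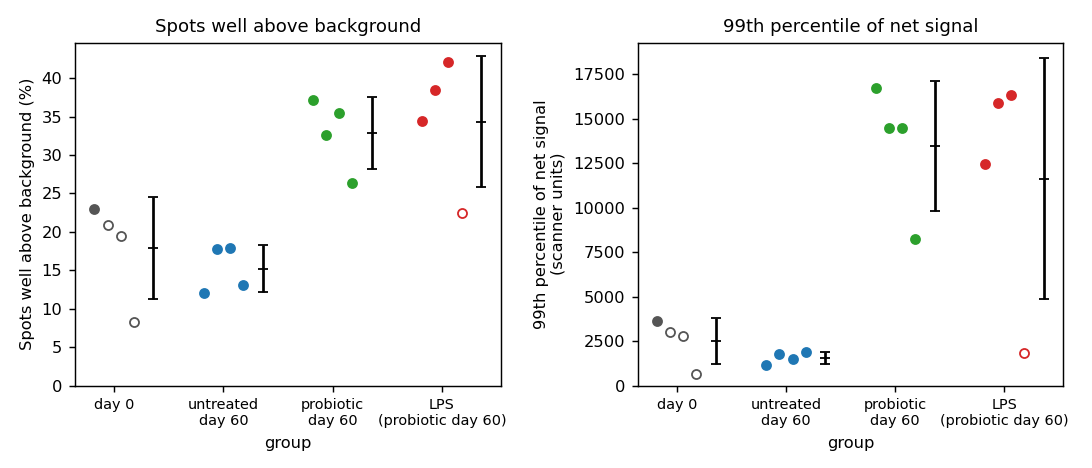
Percent of spots well above background (left) and 99th percentile of net signal in scanner units (right) per array and group; bars are mean and SD of 4 arrays, and open circles are the 4 arrays with multiplicative detrending. The untreated arrays averaged 15.2% and the probiotic arrays 32.9%.

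Probiotic against untreated cows at day 60 asks how blood expression differed with the supplement. The ribosomal protein genes RPS29, RPS3A, RPL4, RPS19 and RPL7 rose by 8.53 ± 1.53, 8.38 ± 1.52, 8.12 ± 1.56, 8.01 ± 1.49 and 7.80 ± 1.44 on the log2 scale (n = 4 arrays per group, adjusted p from 0.00282 to 0.00325). S100A12, a calcium-binding protein of neutrophils, was at least 248-fold higher by the probe used and under the scaling used (adjusted p = 0.00260). Another of its probes was above background on every untreated array. All bounds against the untreated arrays depend on the scaling, since the percentile subtracted on these arrays lay in dim signal. Other scalings moved the balance of rises and falls, as given below. HBG, a globin chain, rose by 8.02 ± 1.58 and BOLA-NC1, a non-classical MHC class I molecule, by 8.01 ± 1.53 (adjusted p = 0.00326 and 0.00325).

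Genes lower in the probiotic pool included NPY, the neurotransmitter neuropeptide Y, which fell by 4.40 ± 1.39 (adjusted p = 0.0264), and CSPG4, a membrane proteoglycan, which fell by 4.28 ± 1.09 (adjusted p = 0.0103). NRGN, a calmodulin-binding protein, and ZMAT3, an RNA-binding zinc finger protein, changed by -4.16 ± 1.14 and -4.15 ± 1.26. SSPO, a spondin, RNF186, a ubiquitin ligase, and MRS2, a mitochondrial magnesium channel, changed by -4.02 ± 1.36, -4.01 ± 1.45 and -3.96 ± 1.07 (adjusted p from 0.0137 to 0.0468 over these 5 genes). With each of the 8 arrays left out in turn, SSPO and RNF186 never passed, NPY and ZMAT3 each failed in 6 cases and NRGN in 1 (adjusted p up to 0.105). With all arrays kept, limma on the signal before detrending gave SSPO, RNF186, NPY, ZMAT3 and NRGN adjusted p from 2.13e-06 to 0.00796. ANXA11, a calcium-dependent membrane-binding protein, fell by 4.69 ± 1.24 (adjusted p = 0.0123), but the mean of its probes was 0.85.

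Camera called 3 lists up in the probiotic pool, and none of these calls held with an estimated correlation (adjusted p = 0.987 with an estimated correlation for each). Of 68 ribosomal protein genes, 45 rose, 2 fell and 21 did not pass (56 up and 2 down adjusted over the list alone), with a median of 5.78, or 6.15 with dim members at their bound (camera adjusted p = 2.57e-10). RPSA rose by 9.17 ± 1.42, and RPS26 and RPL10 were, by the probes used, at least 194-fold and 357-fold higher (adjusted p from 0.00256 to 0.00257). On the arrays, 60 of these genes were above background on all probiotic arrays and 36 on all untreated arrays. Of 34 oxidative phosphorylation genes, which make ATP in mitochondria, 19 rose, 0 fell and 15 did not pass (25 and 0 adjusted over the list alone; median 4.22, or 3.67 at the bounds; camera adjusted p = 7.02e-05). The ATP synthase subunits ATP5F1B and ATP5F1A were, by the probes used, at least 203-fold and 84.8-fold higher, and COX4I1 of cytochrome c oxidase rose by 8.14 ± 1.81 (adjusted p from 0.00257 to 0.00513). For COX4I1, untreated replicate 4 lay apart from the rest of its group. Of 18 MHC class II genes, which present peptides to helper T cells, 10 rose, 1 fell and 7 did not pass (12 and 1 adjusted over the list alone; median 4.59, or 3.97 at the bounds; camera adjusted p = 0.0224). BOLA-DQA5 was at least 61.3-fold higher, and BOLA-DQB1 and the protease CTSS rose by 7.19 ± 1.68 and 7.13 ± 1.64 (adjusted p from 0.00257 to 0.00666). Before detrending the counts were 58 up and 4 down for ribosomal proteins, 28 up and 1 down for oxidative phosphorylation and 15 up and 2 down for class II. The medians of these 3 lists stayed above 0 under each of the 7 scaling and background alternatives, with their lowest values under cyclic loess (2.09, 0.93 and 1.09). Camera no longer called the class II list after quantile normalization (adjusted p = 0.347), with normexp and quantile normalization (0.0663) or before detrending (0.154; range over the alternatives 0.00506 to 0.987).

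For the immune response lists, the numbers below are genes that rose and fell of those measured, with the counts adjusted over the list alone and those before detrending in parentheses. Inflammatory cytokines and chemokines had 2 and 1 of 9 (3 and 3, 5 and 4), NF-kB feedback genes 2 and 0 of 14 (2 and 0, 10 and 0) and Toll-like receptor signalling 4 and 0 of 22 (2 and 0, 16 and 1). Interferon-stimulated genes had 7 and 2 of 22 (10 and 2, 13 and 4), immediate early genes 3 and 1 of 15 (6 and 1, 8 and 6) and heat shock proteins 5 and 2 of 15 (6 and 3, 11 and 3). Antimicrobial proteins had 3 and 1 of 14 (5 and 2, 10 and 3). Cell type markers are counted the same way. Neutrophil markers had 6 and 2 of 20 (6 and 3, 10 and 6), monocyte markers 4 and 1 of 9 (5 and 1, 5 and 1) and T cell markers 4 and 1 of 19 (4 and 1, 13 and 2). B cell markers had 8 and 1 of 13 (9 and 2, 10 and 3), natural killer and cytotoxic genes 2 and 1 of 11 (2 and 1, 5 and 4) and erythroid genes 1 and 0 of 11 (1 and 0, 6 and 0). Platelet genes had 1 and 1 of 9 (1 and 1, 4 and 2) and eosinophil and basophil markers 1 and 0 of 3 (1 and 0, 2 and 0). Helper T cell cytokines and regulators had 0 and 1 of 11 (0 and 0, 5 and 3), Wnt signalling 1 and 0 of 16 (0 and 0, 4 and 1) and lipid metabolism 9 and 0 of 29 (10 and 0, 18 and 0). Cell cycle had 2 and 1 of 14 (2 and 0, 7 and 2). Camera called none of these 19 lists (lowest adjusted p = 0.454). The sign of the median turned under at least 1 scaling or background alternative for inflammatory cytokines and chemokines, NF-kB feedback genes, immediate early genes, heat shock proteins, monocyte markers, natural killer and cytotoxic genes, erythroid genes, platelet genes, helper T cell cytokines and regulators, antimicrobial proteins, Wnt signalling and cell cycle. In the immune response lists, BIRC3, an inhibitor of apoptosis, and IRAK1, a Toll-like receptor kinase, were at least 28.9-fold and 25.0-fold higher (adjusted p from 0.00395 to 0.00589). MX1, an antiviral GTPase, and KLF6, a transcription factor, were at least 27.5-fold and 45.6-fold higher (adjusted p from 0.00334 to 0.00611). The chaperone HSPA8 rose by 6.96 ± 1.78 (adjusted p = 0.0104). Its log2 signal was -0.87, -0.30 and 0.52 on untreated replicates 1, 2 and 3, and 6.77 on untreated replicate 4. The chemokine CCL4 was at least 8.87-fold lower (adjusted p = 0.0153; above background on 3 of 4 untreated arrays; at least 17.1-fold without untreated replicate 4). In the marker lists, SIRPA of monocytes and CD247 of the T cell receptor were at least 71.6-fold and 66.7-fold higher (adjusted p from 0.00310 to 0.00334). GNLY, a cytotoxic granule protein, and the clotting factor F13A1 were at least 42.1-fold and 77.4-fold higher (adjusted p from 0.00257 to 0.00326), and the lipoxygenase ALOX15 rose by 7.01 ± 1.61 (adjusted p = 0.00598). The transcription factor IRF4 fell by 3.39 ± 1.08 (adjusted p = 0.0278). GSK3B of Wnt signalling was at least 6.48-fold higher, the fatty acid elongase ELOVL5 at least 28.8-fold and RRM1, which makes deoxyribonucleotides, at least 18.2-fold (adjusted p from 0.00343 to 0.0276). IL1B, an inflammatory cytokine, was at least 5.39-fold higher (adjusted p = 0.0336; above background on 3 of 4 probiotic arrays). Its bound was 2.60-fold or 2.53-fold without probiotic replicate 2 or 3 and 8.17-fold or 15.7-fold without replicate 1 or 4. With 1 of the 8 arrays left out, IL1B and IRF4 each failed in 6 cases and GSK3B in 7 (adjusted p up to 0.130). Further probes of IL1B, S100A12, ATP5F1B and RPL10 were above background on every untreated array, and those of F13A1, RPS26, BIRC3, KLF6, ATP5F1A and RRM1 on 1 or 2. IL10 did not pass (adjusted p = 0.150). TLR4, with the probe used dim on all untreated arrays, and CD14, with -1.65, did not pass (adjusted p = 0.953 and 0.327), and the fitted sign for TLR4 turned under 5 scaling or background alternatives and that for CD14 when scaled to the median.

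In this comparison 2337 of 9413 genes passed in limma, 1716 up and 621 down, and the median over all tested genes was 1.53. The probe was dim on all untreated arrays in 1275 of these genes and on all probiotic arrays in 262. The direction went with the place on the array: 900 of 924 calls were up in the outer rows and 170 of 516 in the middle rows. Scaling moved the shares of up and down: 4614 (4405 up, 209 down) passed when scaled to the median and 3245 (786 up, 2459 down) with cyclic loess. With normexp and quantile normalization 5337 (3384 up, 1953 down) passed, when scaled on probes detected everywhere 4457 (1831 up, 2626 down), and by the authors' averages 1844 (113 up, 1731 down) reached the fold. None of these 8 arrays was detrended, and every gene named above as changed also passed on the signal before detrending. The standard errors and p-values still took in the spread of the detrended day 0 and LPS arrays, since 1 fit held all groups. RPS29 rose by 8.53 on both signals, with a standard error of 1.53, and of 0.59 before detrending. In limma 6800 genes passed before detrending and 6591 with these 2 groups alone. Median and mean differed in sign for natural killer genes (-0.61 and 0.50) and Wnt signalling (-0.21 and 0.45). Camera sets a list against all other genes, and its direction differed from the sign of the median in 7 lists here. It did so in 12 lists for probiotic against day 0, 11 for LPS and 13 for untreated against day 0.

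**Figure D2:**
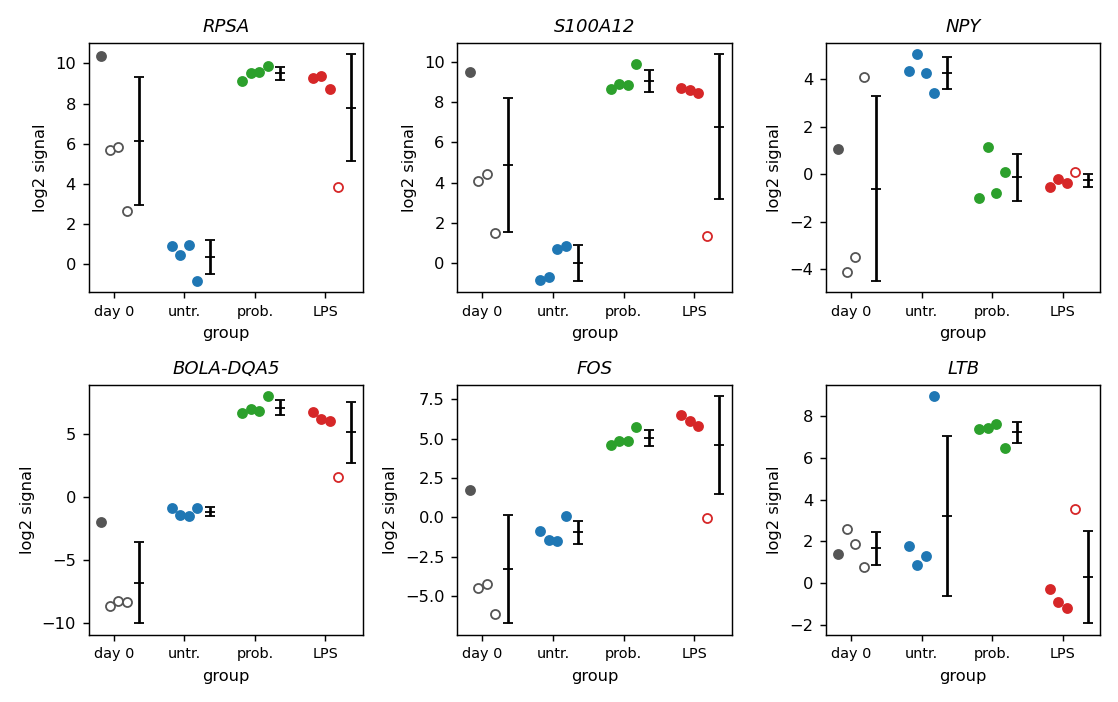
Log2 signal, relative to each array's 75th percentile, of 6 named genes on the 16 arrays; points are arrays, bars are mean and SD of 4 arrays, and open circles are the 4 arrays with multiplicative detrending. In the probiotic against the untreated group, S100A12 was at least 248-fold higher by the probe used and under this scaling. NPY fell by 4.40 ± 1.39 on the log2 scale. Another probe of S100A12 was above background on every untreated array.

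Probiotic at day 60 against day 0 asks what changed over the 60 days of supplementation. BOLA-DQA5, an alpha chain of MHC class II, was at least 70.3-fold higher at day 60 on the signal before detrending (adjusted p = 9.49e-06, n = 4 arrays per group), and its probe was above background on all probiotic and on no day 0 arrays. FOS, a transcription factor subunit induced within minutes of a stimulus, rose by 8.29 ± 1.51, and DUSP1, a phosphatase that turns off MAP kinases, by 7.83 ± 1.48. LENG8 rose by 8.41 ± 1.55, and the neutrophil chemokine GRO1 was at least 2.69-fold higher before detrending (adjusted p = 0.00344 for each of these 4 genes). STRN3, a scaffold of phosphatase complexes, and CYTH2, an activator of ARF GTPases, changed by -4.22 ± 1.14 and -3.90. CHCHD6 of mitochondrial cristae and LRCH4 changed by -3.05 ± 1.04 and -2.92 ± 1.01 (adjusted p from 0.00447 to 0.0143 over these 4 falls; CHCHD6 failed without day 0 replicate 2 or probiotic replicate 1, at up to 0.0592). These 9 genes also passed on the signal before detrending, with log2 changes of 7.91, 3.58, 1.93, 1.93, 3.20, -3.14, -4.47, -2.76 and -2.88.

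Other large rises did not pass before detrending. They were in DNAAF2, a dynein assembly factor (8.16 ± 1.81), AP2A2, a clathrin adaptor (7.94 ± 1.81), and RNF166, a ubiquitin ligase (7.68). The others were the splicing factor SRSF2 (7.61) and NUP188 of the nuclear pore (7.58). Limma gave adjusted p = 0.00344 for each of these 5 genes, and their changes before detrending ran from 0.37 to 1.07. ANXA11 fell by 3.74 ± 1.24 and passed on both signals. METTL2A, a transfer RNA methyltransferase, and ANXA6, a membrane-binding annexin, changed by -3.96 ± 1.14 and -3.12 ± 1.18 (adjusted p from 0.00572 to 0.0223 over these 3 falls; ANXA6 failed without day 0 replicate 2 or 3 or probiotic replicate 3, at up to 0.0675). The mean of a gene's probes was above 0 for ANXA11, METTL2A and ANXA6 (2.25, 1.19 and 1.96). In the lists, none of the following 20 genes passed before detrending. NFKBIA, the inhibitor of NF-kB, rose by 6.92, the transcription factor IRF5 by 6.06 and the antiviral OAS1Y by 6.86. The chaperone DNAJB6 rose by 8.56 and the chemokine receptor CXCR2 of neutrophils by 8.26. CTSS rose by 6.36, FCRLA of B cells by 8.05, NKG7 of killer cells by 6.36 and ALOX15 by 6.76. TNFRSF4 of activated T cells rose by 6.80, APC of Wnt signalling by 5.61 and the lipid droplet protein PLIN2 by 6.60, and the mitotic kinase BUB1 passed upward with no fold given (adjusted p from 0.00325 to 0.00747 over these 13 genes). A rise was also called for TRAT1, SLC25A37, F13A1, BPI, CYC1, RPL13 and CD14, by 6.74, 6.37, 5.93, 6.33, 6.42, 6.85 and 4.30, but the sign of each turned under at least 1 scaling or background alternative (adjusted p from 0.00344 to 0.00725). IL1B, IL10 and TLR4 did not pass, with 2.46, -0.58 and 2.01 (adjusted p = 0.136, 0.628 and 0.102), and their signs turned under such alternatives too.

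For the immune response lists, the counts that rose and fell of those measured, and adjusted over the list alone and then before detrending in parentheses, were these. Inflammatory cytokines and chemokines had 4 and 1 of 9 (4 and 1, 1 and 1), NF-kB feedback genes 11 and 0 of 14 (11 and 0, 1 and 0) and Toll-like receptor signalling 18 and 0 of 22 (18 and 0, 0 and 0). Interferon-stimulated genes had 14 and 0 of 22 (13 and 0, 0 and 1), immediate early genes 8 and 0 of 15 (7 and 0, 2 and 1) and heat shock proteins 7 and 3 of 15 (9 and 3, 0 and 3). Antimicrobial proteins had 9 and 1 of 14 (9 and 1, 0 and 1). Cell type markers are counted the same way. Neutrophil markers had 13 and 3 of 20 (13 and 3, 0 and 2), monocyte markers 8 and 0 of 9 (8 and 1, 0 and 1) and T cell markers 14 and 1 of 19 (14 and 1, 1 and 1). B cell markers had 9 and 1 of 13 (10 and 1, 0 and 1), natural killer and cytotoxic genes 7 and 1 of 11 (7 and 1, 0 and 1) and erythroid genes 8 and 1 of 11 (8 and 1, 0 and 2). Platelet genes had 4 and 0 of 9 (3 and 0, 0 and 0) and eosinophil and basophil markers 3 and 0 of 3 (3 and 0, 0 and 0). Helper T cell cytokines and regulators had 7 and 1 of 11 (7 and 1, 0 and 1), Wnt signalling 9 and 0 of 16 (9 and 0, 1 and 2) and lipid metabolism 22 and 1 of 29 (22 and 1, 0 and 1). Cell cycle had 10 and 0 of 14 (11 and 0, 0 and 0), MHC class II genes 15 and 1 of 18 (16 and 1, 1 and 1) and oxidative phosphorylation 27 and 0 of 34 (27 and 0, 1 and 0). Ribosomal proteins had 48 and 4 of 68 (48 and 4, 8 and 4). Camera called no list in this comparison (lowest adjusted p = 0.454). The sign of the median turned under at least 1 scaling or background alternative for inflammatory cytokines and chemokines, heat shock proteins, erythroid genes, platelet genes, helper T cell cytokines and regulators, antimicrobial proteins, Wnt signalling, ribosomal proteins and cell cycle. In all 6874 of 9413 genes passed in limma, 6541 up and 333 down, around a median over all genes of 4.38. On 2 alternatives chosen after seeing the data, 602 (218 up, 384 down) passed before detrending and 275 (120 up, 155 down) without the 4 detrended arrays, which leaves 1 day 0 array, so that the spread comes from the other groups. The first had a median of 0.30 and shared 341 genes in the same direction. The shares also moved with scaling: 5390 (4160 up, 1230 down) passed with cyclic loess, 223 (160 up, 63 down) with normexp and quantile normalization and 4907 (3550 up, 1357 down) when scaled on probes detected everywhere. The share of genes that passed went from 98.0% in the outer rows of the array to 33.9% in the middle.

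Untreated at day 60 against day 0 compares pools 60 days apart, neither with the supplement. Whether the day 0 pool holds the untreated cows stays open, so a change over time in these cows is not established. Among ribosomal protein genes, RPSA fell by 5.80 ± 1.42, RPL31 fell by 5.25 ± 1.45, and RPS26 was at least 11.7-fold lower (n = 4 arrays per group, adjusted p from 0.00598 to 0.0159); without day 0 replicate 1 or 4 the bound for RPS26 was 4.41-fold or 27.8-fold. DEFB122, an antimicrobial defensin, rose by 7.32 ± 1.25, JUN, the partner of FOS, by 5.65 ± 1.28, and FOXP3, the transcription factor of regulatory T cells, was at least 1.37-fold higher before detrending, with signal above background on 3 of 4 untreated arrays (adjusted p from 0.000865 to 0.00424). CLDN7 of tight junctions rose by 6.70 ± 1.35, NFKBIL1, an inhibitor of NF-kB, by 6.65 ± 1.41, and MIIP, an inhibitor of cell migration, by 6.57 ± 1.33 (adjusted p from 0.00250 to 0.00330). These 9 genes also passed before detrending, with log2 changes of -9.53, -8.92, -9.08, 2.99, 3.13, 1.52, 1.15, 1.09 and 1.28.

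Further rises did not pass before detrending. TBX21, the transcription factor of T helper 1 cells, rose by 6.77 ± 1.45 and LPIN3, a phosphatidate phosphatase, by 6.59. The repressors MIER2 and NAB2 rose by 6.46 and 6.44, and the immune regulator BATF2 by 6.38 (adjusted p from 0.00311 to 0.00402 over these 5 genes). CD14, the LPS co-receptor of monocytes, rose by 5.95 ± 1.30, and PAX5 of B cells by 3.80. AHSP, a globin chaperone, rose by 5.86, THBS1 of platelets by 5.46 and the cholesterol transporter ABCG1 by 5.98 (adjusted p from 0.00373 to 0.0315 over these 5 genes). CX3CR1 of monocytes rose by 4.95 and the Wnt receptor FZD7 passed upward with signal on 1 of 4 untreated arrays, but both were below 0 before detrending (adjusted p = 0.0277 and 0.00751). The T cell co-stimulator CD28 and BOLA-DYB of MHC class II also passed upward, each above background on 2 of 4 untreated arrays (adjusted p = 0.00524 and 0.00336), and BOLA-DYB passed before detrending too. No fold is given for FZD7, CD28 and BOLA-DYB, since none could be set before detrending. CSF1, BCL3, TICAM1, OAS2, KIT and BUB1 passed with a probe dim in both groups, so no fold is given. DNAJB6 and CXCR2 passed with a probe dim on all untreated arrays though fitted up, and no fold is given for them either. For all of these 8 genes but TICAM1 the sign turned under scaling or background alternatives. With 1 of the 8 arrays left out, DNAJB6 and CXCR2 each failed in 7 cases, CX3CR1 in 6, PAX5 in 5 and BCL3 in 2 (adjusted p up to 0.183). IL1B, IL10 and TLR4 did not pass (IL10 1.42; the probes used for IL1B and TLR4 dim on all untreated arrays; adjusted p = 0.338, 0.338 and 0.161), and the sign for TLR4 turned before detrending and with normexp.

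Camera called 3 lists down against day 0, none of them with an estimated correlation (adjusted p = 0.987 with an estimated correlation for each). Of 68 ribosomal protein genes, 0 rose, 7 fell and 61 did not pass (0 and 2 adjusted over the list alone; camera adjusted p = 2.06e-27). Their median was -1.96, or -1.63 at the bounds, and stayed below 0 under each of the 7 scaling and background alternatives. None of 34 oxidative phosphorylation genes passed (0 and 0 adjusted over the list alone); their median was -0.00305, or 0.34 at the bounds, below the median of all genes (camera adjusted p = 1.85e-06). Of 15 heat shock genes 1 passed, upward and without a fold (DNAJB6), and the list was called down with a median of -0.40 and a mean of 0.17 (camera adjusted p = 0.00632). That adjusted p was 0.218 after quantile normalization, 0.171 with normexp and quantile normalization and 0.376 before detrending (range over the alternatives 0.00197 to 0.987). Before detrending the counts were 1 up and 52 down for ribosomal proteins, 1 up and 23 down for oxidative phosphorylation and 0 up and 11 down for heat shock, with medians of -6.24, -4.45 and -3.22. On the untreated arrays 15.2% of spots were well above background.

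For the other immune response lists, these are the counts that rose and fell, with those adjusted over the list alone and those before detrending in parentheses. Inflammatory cytokines and chemokines had 3 and 0 of 9 (3 and 0, 3 and 2), NF-kB feedback genes 1 and 0 of 14 (1 and 0, 0 and 9) and Toll-like receptor signalling 3 and 1 of 22 (2 and 1, 0 and 15). Interferon-stimulated genes had 3 and 0 of 22 (2 and 0, 3 and 12), immediate early genes 4 and 0 of 15 (5 and 0, 4 and 7) and antimicrobial proteins 2 and 1 of 14 (2 and 1, 2 and 9). Cell type markers are counted the same way. Neutrophil markers had 3 and 1 of 20 (1 and 0, 3 and 9), monocyte markers 2 and 0 of 9 (2 and 0, 0 and 7) and T cell markers 3 and 0 of 19 (1 and 0, 2 and 12). B cell markers had 2 and 0 of 13 (0 and 0, 1 and 10), natural killer and cytotoxic genes 3 and 0 of 11 (6 and 0, 3 and 4) and erythroid genes 4 and 0 of 11 (6 and 0, 0 and 6). Platelet genes had 1 and 0 of 9 (1 and 0, 1 and 4) and eosinophil and basophil markers 2 and 0 of 3 (2 and 0, 0 and 1). Helper T cell cytokines and regulators had 4 and 0 of 11 (4 and 0, 3 and 3), Wnt signalling 6 and 0 of 16 (6 and 0, 3 and 5) and lipid metabolism 6 and 0 of 29 (10 and 0, 0 and 15). Cell cycle had 3 and 0 of 14 (3 and 0, 2 and 7) and MHC class II genes 2 and 0 of 18 (2 and 0, 1 and 13). Camera called none of these 19 (lowest adjusted p = 0.444), and the median of each turned sign under at least 1 scaling or background alternative. In all 2490 genes passed in limma, 2456 up and 34 down, around a median over all genes of 1.99. The probe was dim on all day 0 arrays in 1218 of them and on all untreated arrays in 868. Before detrending 6164 (1415 up, 4749 down) passed around a median of -1.70, with 545 genes shared in the same direction. Cyclic loess gave 3411 (3000 up, 411 down) and scaling on probes detected everywhere 3475 (2849 up, 626 down). Normexp gave 4496 (1808 up, 2688 down) with quantile normalization and 3491 (1146 up, 2345 down) with the 75th percentile. Leaving out day 0 replicate 1, the only day 0 array without detrending, gave 5469 genes, and leaving out day 0 replicate 2, 3 or 4 gave 1230, 1304 or 1543.

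Genes shared between comparisons tell whether the probiotic pool differed from both other pools. In all 1864 genes differed in the same direction from untreated and from day 0, 1607 up and 257 down, against 1192 and 22.0 expected from the counts alone. The comparisons share the probiotic arrays, and with these split between them the count averaged 177 over 6 splits (range 105 to 247), against 109 up and 2.02 down expected. Simulated unchanged groups that share arrays gave 0, which says nothing on calls shared where genes change. The covariance of the log2 changes was 5.84 against 1.03 simulated, and their correlation 0.692 against 0.499. With the probiotic arrays split the covariance averaged 5.67. The simulated noise was independent between genes and arrays and held no array-wide effects such as detrending. A covariance above the simulated one therefore does not show that the pools share a change. BOLA-DQA5, F13A1, ALOX15 and CTSS rose and ANXA11 fell in both comparisons, though the sign of ANXA11 turned with the mean of its probes and that of F13A1 against day 0 with normexp and quantile normalization. Against day 0, F13A1, ALOX15 and CTSS did not pass before detrending. Against day 0, 2116 genes differed in the same direction in the untreated and the probiotic pool, 2115 up and 1 down, against 1707 up expected. With the day 0 arrays split the count averaged 44.3 (range 1 to 106), against 40.9 up expected. Simulated unchanged groups gave 0 here too. The covariance was 2.23 against 1.03 simulated, and averaged 1.32 with the day 0 arrays split, but the correlation, 0.343, was below the 0.499 of unchanged groups. CD14 rose in both, but in the probiotic comparison its sign turned before detrending and with normexp and quantile normalization. Before detrending the shared counts were 388 and 216; leaving out day 0 replicate 1 gave 3882 and 5009.

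LPS against probiotic at day 60 was the positive control, blood of the same cows with and without endotoxin. The ribosomal protein genes RPL7A and RPL5 were at least 319.9-fold and 111-fold higher with LPS, and RPS27 rose by 8.39 ± 1.25 (n = 4 arrays per group, adjusted p = 6.42e-05, 0.000691 and 0.00221). Without LPS replicate 3 the bound for RPL7A was 185-fold, and without LPS replicate 4 the bounds were 547-fold and 174-fold. Another probe of RPL5 was above background on 3 of 4 probiotic arrays. The probe used for RPS27 was so on 1 of 4 probiotic arrays, so the size of its rise rests largely on signal near background. LTB, a membrane-bound cytokine of the TNF family, fell by 6.95 ± 1.48 (adjusted p = 0.0492), but failed in 7 of 8 cases with 1 array left out (up to 0.278). Among genes outside the naming rule, chosen after their values were seen, TALDO1 of the pentose phosphate pathway fell by 7.02 ± 1.44 (adjusted p = 0.0374). Its probe was above background on 1 of 4 LPS arrays. PDCD4, an inhibitor of translation, was at least 39.6-fold higher (adjusted p = 0.00712). IL1B, IL10, TLR4 and CD14 did not pass, with 0.69, -0.68, 1.34 and -0.69 (adjusted p = 0.783, 0.715, 0.698 and 0.752). The signs for IL10 and CD14 turned under 2 scaling or background alternatives each, and that for IL1B with the mean of its probes. TNF, IL6, CXCL8 and TLR2 were not tested in any comparison. No probe of TNF or IL6 was well above background on any array, and those of CXCL8 and TLR2 were so on at most 3 of the 4 arrays of a group.

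Of the lists, ribosomal proteins had 3 genes up and 0 down of 68 (3 and 1 adjusted over the list alone), and in the other 21 lists 0 genes passed. Adjusted over the list alone, 2 heat shock genes, 2 erythroid genes, 1 monocyte marker and 1 cell cycle gene were up. Before detrending 3 ribosomal protein genes were up and 1 down; 1 gene each was up in the heat shock, monocyte, erythroid and cell cycle lists, 1 T cell marker was down, and the other 16 lists had 0. Camera called no list (lowest adjusted p = 0.198). The sign of the median turned under at least 1 scaling or background alternative for inflammatory cytokines and chemokines, immediate early genes, heat shock proteins, neutrophil markers, helper T cell cytokines and regulators, antimicrobial proteins, Wnt signalling and ribosomal proteins. The cytokine list had a median of 0.13 and a mean of -0.0867. In all 21 genes passed in limma, 19 up and 2 down, and 271 had an unadjusted p under 0.05. The median over all genes was -1.18, and the probe was dim on all probiotic arrays in 16 of the 21. None lay in the outer 53 rows at each edge of the array, where 7.88 were expected, and 19 lay in the middle rows. Before detrending 108 (90 up, 18 down) passed, and the fit of these 2 groups alone, which share a scan day, gave 33 (30 up, 3 down). With normexp and the 75th percentile 31 (23 up, 8 down) passed, and by the authors' averages 6191 (663 up, 5528 down) reached the fold.

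**Figure D3:**
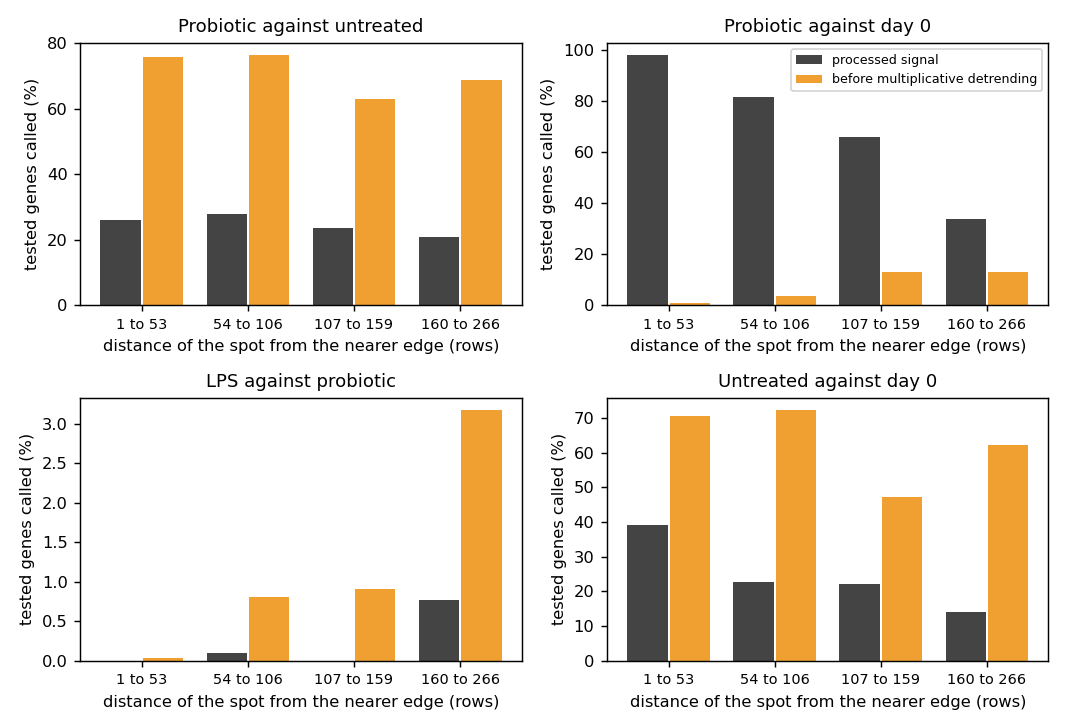
Percent of tested genes that passed, by distance of the spot from the nearer edge of the array in rows, in the 4 comparisons; dark bars are the processed signal and orange bars the signal before multiplicative detrending. For probiotic against day 0 the share fell from 98.0% in the outer rows to 33.9% in the middle, and before detrending it was 12.9% in the middle.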

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

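The counts of splits were fixed before the results were seen, and the tests of detrending, of a change over the 60 days, of uneven signal, of an LPS response, of cell makeup and of weak hybridisation were chosen after. An array is listed below where its distance to the nearest other array of its group, divided by the group's range, passed Dixon's 95% value for 4 arrays; chance alone marks about 1 in 20 groups. This held for 8 of 26 array measures and 29 of 223 groups of a named gene, against 11.2 expected by chance, and day 0 replicate 1 accounts for 16 of the latter and probiotic replicate 4 for 6. LPS replicate 4 stood apart in negative control signal (0.982), in correlation with its group (0.903) and in correlation with probiotic replicate 2 over the outer rows (0.937). Day 0 replicate 4 did so in the correlation with its group (0.901) and with probiotic replicate 2 over outer (0.959) and middle rows (0.900), day 0 replicate 1 in its brightest spike-in signal (0.861), and probiotic replicate 4 in the correlation with its group (0.958).

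Day 0 replicate 1, the only day 0 array without detrending, stood apart in DUSP1 (0.862), NKG7 (0.836), BOLA-DQA5 (0.936), PLIN2 (0.865), CYC1 (0.923), TLR4 (0.836), TBX21 (0.941), NFKBIL1 (0.882), MIIP (0.859), NAB2 (0.901), CSF1 (0.900), TICAM1 (0.885), JUN (0.864), CD28 (0.877), THBS1 (0.950) and FOXP3 (0.950). These ratios are on the processed signal. Before detrending, BOLA-DQA5 had a log2 signal of -1.35 on day 0 replicate 1, and of -0.98, -1.01 and -0.02 on replicates 2, 3 and 4. Probiotic replicate 4 stood apart in NRGN (0.922), RNF186 (0.845), CD14 (0.864), GRO1 (0.840), NFKBIA (0.933) and TRAT1 (0.836), and untreated replicate 4 in CCL4 (0.932), COX4I1 (0.900), PAX5 (0.897) and RPL31 (0.923). Untreated replicate 3 stood apart in TLR4 (0.884), untreated replicate 1 in BOLA-DYB (0.851) and LPS replicate 4 in IL10 (0.834). Both day 60 pools have the same day 0 pool, which cancels when their changes from day 0 are compared. The 2337 genes flagged by limma for that difference are therefore the comparison of these pools at day 60 again, and no separate test of a change from day 0. For IL1B, this difference was at least 5.39-fold under the scaling used. Outside the genes, the brightest spike-in control spots reached a signal of 119174 on LPS replicate 3 and of 136 on probiotic replicate 4, and lay between 100.1 and 136 on the untreated arrays.

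Most tested genes were brighter at day 60 than at day 0, with a median log2 change of 4.38 in the probiotic pool. A change in the cows over the 60 days, with the supplement or without it, is argued against as the source of the whole shift: before detrending, the highest of the medians against the 4 single day 0 arrays was 0.89. The multiplicative detrending of 3 of the 4 day 0 arrays may account for the shift, which these arrays showed only with the detrending. Against day 0 replicates 2, 3 and 4 the medians were 5.43, 5.11 and 6.77 with it, and -0.15, -0.03 and 0.89 before it. The median was 0.19 without the detrended arrays, which leaves day 0 replicate 1 alone. Chance cannot be excluded for either count: of 35 splits of the arrays, 2 called as many genes as the real 6874 for probiotic against day 0 (highest other 7229), and 5 as many as the real 2490 for untreated against day 0 (highest other 4654). The highest other splits set day 0 replicate 1, which had no detrending, together with 3 arrays of the day 60 pool, which points to this structure of the samples.

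Abundant blood transcripts were dim on the untreated arrays, and 2337 genes differed from the probiotic pool. Of 35 splits of the 8 arrays only the real split, 1 in all, called as many (highest other 1). This argues against chance among repeat arrays for that count. It is also the lowest share that 35 splits can give, and every other split mixes the slides. With 1 pool per group, chance differences between pools or cows were not tested. Another cell makeup of the untreated cows' blood was tested on the ribosomal protein genes, whose median difference was 5.78. These genes are part of the pattern itself, so this value cannot decide and cell makeup stays open. Weak hybridisation on the untreated slide may account for the dimness: the median correlation between these 4 arrays of 1 pool was 0.485, against 0.839 in the probiotic and 0.619 in the LPS group. That correlation takes in probes bright on any of the 16 arrays, so dimness itself can lower it and it cannot decide. The negative controls had a net signal of 117 ± 4.00 (SD, n = 4) on the untreated arrays. Means in the day 0, probiotic and LPS groups were 59.7, 61.7 and 69.4. Slide and group cannot be told apart, so an effect of the supplement on single genes stays open and untested.

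Of the 21 genes called with LPS, 19 lay in the middle rows of the array. A response to LPS alone is argued against as the source of the place of these calls, since a blood response does not depend on the row of a spot. In the outer rows lay 0 of 21 calls where 7.88 were expected (one-sided exact hypergeometric p = 5.04e-05, a test chosen after the place was seen). Before detrending, 1 of 108 calls lay in the outer rows, with 3533 tested genes, and 78 in the middle rows, with 2462. Whether single calls hold a response to LPS stays open. Uneven signal in the middle of the arrays was tested on probiotic replicate 4 against the other arrays of its pool: with the offset between arrays left in, the share of genes 2-fold apart in middle over outer rows was 0.949, which cannot tell. With the offset removed, a test chosen after the first was seen, the ratio was 8.06 (43.4% against 5.38%), so the signal of that array was uneven in the middle rows. In 16 of the 21 genes the probe was dim on all probiotic arrays. Unevenness of 1 array therefore does not show how these calls arose, and uneven signal stays open as their source. Of 35 splits only the real split, 1 in all, called 21 genes (highest other 1), which argues against chance among repeat arrays. It is also the lowest share that 35 splits can give, and every other split mixes the slides. With 1 array left out the count ran from 7 to 41. Chance differences between the 2 pools were not tested.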

How the results depend on the processing

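The alternatives on detrending, on normexp, on scaling over probes detected everywhere, on the array's rows and on leaving out several arrays together were chosen after the results were seen. Without the 4 detrended arrays, day 0 keeps 1 array and the spread comes from the other groups. The cause was not tested for the changes below unless it is named. Signal over background limits the tests: 671 of 43653 probes were well above background on all 16 arrays, and the untreated and day 0 pools had few bright spots. In simulated data, with noise at the residual spread of all 16 arrays, changes of 4 on the log2 scale were found in 14% to 20% of cases. Changes of 8 were found in 72% to 90% and changes of 2 or less in 0%, with limma. That spread includes the detrended arrays. For the 132 named results there were 2148 alternative values: 1800 had the same sign and side of the threshold, 265 no longer passed, 23 newly passed and 60 changed sign. The counts at no fold minimum, at a fold of at least 1.5 and with limma's treat stayed within 1.5 times in all 4 comparisons. Versions of normexp on a mean signal were not run, and the median signal was used instead.

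Genes passing, in the order probiotic against untreated, probiotic against day 0, LPS and untreated against day 0, were 2337, 6874, 21 and 2490. Only counts that moved by more than 1.5 times follow. For probiotic against untreated they were 4880 with quantile normalization and 4614 scaled to the median. They were 5337 and 5501 with normexp (then quantile or the 75th percentile), 6800 before detrending and 4457 scaled on probes detected everywhere. Filters gave 12657 with no filter and 90 with probes above background on all 16 arrays (more and fewer genes tested). Other fits gave 6591 with the 2 groups alone and 7523 with averaged arrays and no test. Other arrays or spots gave 6769 without the detrended arrays, 7095 before detrending without the 4th day 0 and LPS arrays, and 1099 (1084 up, 15 down) in the outer rows alone. For probiotic against day 0 they were 223 and 707 with normexp, 602 before detrending, 14244 with no filter and 511 with all-array probes. They were 275 without the detrended arrays and 1008 before detrending without the 4th arrays. Outer rows gave 3448, then 18 there before detrending and 86 there also without the 4th arrays. For LPS they were 12 with quantile normalization, 60 with cyclic loess, 108 before detrending and 89 scaled on probes detected everywhere. Probe choices gave 68 with no filter, 1 with all-array probes and 45 with every probe on its own. Other fits gave 33 with the 2 groups alone, 6195 with averaged arrays and 6191 with the authors' averages (both without a test). They were 149 without the detrended arrays, 140 before detrending without the 4th arrays, and 0 by limma in the outer rows under each of 3 signals (unadjusted p under 0.05 in 3, 84 and 98). For untreated against day 0 they were 1592 with quantile normalization, 610 scaled to the median, 4496 with normexp and quantile normalization and 6164 before detrending. They were 7635 with no filter, 335 with all-array probes, 105 with the 2 groups alone, 7144 with averaged arrays and 7146 with the authors' averages. Other arrays or spots gave 4890 without the detrended arrays, 6668 before detrending without the 4th arrays and 1476 in the outer rows.

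Lists called by camera went from 3 to 0 for probiotic against untreated and from 3 to 0 for untreated against day 0 with an estimated correlation (lowest adjusted p = 0.987). They went from 0 to 1 for probiotic against day 0 and 0 to 1 for LPS with normexp and quantile normalization. The overlap of the probiotic calls against untreated and day 0, 1864, was 3502 with quantile normalization, 388 before detrending, 182 without the detrended arrays and 177 with the shared arrays split. The overlap of both day 60 pools against day 0, 2116, was 889, 216, 124 and 44 in the same order. Splitting leaves fewer arrays per group.

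Leaving out 1 array gave 1257 to 1769 genes for probiotic against untreated, moved over 1.5 times by probiotic replicates 1 to 4 (1460, 1273, 1259, 1518) and untreated replicates 1 to 3 (1350, 1260, 1257). It gave 5490 to 7883 for probiotic against day 0, with none moving it so far. It gave 7 to 41 for LPS, moved by probiotic replicates 1 to 3 (12, 9, 7) and LPS replicates 2 to 4 (10, 8, 41). It gave 1230 to 5469 for untreated against day 0, moved by day 0 replicates 1 to 4 (5469, 1230, 1304, 1543). Called lists stayed at 3, 0 and 3, and with LPS went from 0 to 1 without LPS replicate 4. The first overlap ran from 1017 to 3882, moved by day 0 replicate 1 (3882), probiotic replicates 1 to 4 (1194, 1023, 1017, 1124) and untreated replicates 1 to 3 (1126, 1037, 1030). The other ran from 949 to 5009, moved by day 0 replicates 1 to 4 (5009, 949, 1017, 1149). TLR4 in probiotic against untreated ran from -0.30 to 0.34, changing sign without probiotic replicate 4 or untreated replicate 3. IL1B with LPS ran from -0.85 to 1.78, changing sign without probiotic replicate 4 or LPS replicate 3. The named genes that no longer passed without 1 array follow, with the arrays and the highest adjusted p. For probiotic against untreated they were GSK3B (probiotic replicates 1 to 4 and untreated replicates 1 to 3; 0.0655), IL1B (probiotic replicates 2 and 3 and untreated replicates 1 to 4; 0.130), IRF4 (probiotic replicates 1 to 3 and untreated replicates 1 to 3; 0.0782), NPY (probiotic replicates 1, 3 and 4 and untreated replicates 1 to 3; 0.0721). Further ones were NRGN (probiotic replicate 2; 0.0505), RNF186 (probiotic replicates 1 to 4 and untreated replicates 1 to 4; 0.105), SSPO (probiotic replicates 1 to 4 and untreated replicates 1 to 4; 0.0876), ZMAT3 (probiotic replicates 1 to 3 and untreated replicates 1, 3 and 4; 0.0624). For probiotic against day 0 they were ANXA6 (day 0 replicates 2 and 3 and probiotic replicate 3; 0.0675), CHCHD6 (day 0 replicate 2 and probiotic replicate 1; 0.0592). For LPS it was LTB (probiotic replicates 1 to 4 and LPS replicates 1 to 3; 0.278). For untreated against day 0 they were BCL3 (day 0 replicates 2 and 3; 0.0711), CX3CR1 (day 0 replicates 2 to 4 and untreated replicates 1 to 3; 0.1002), CXCR2 (day 0 replicates 2 to 4 and untreated replicates 1 to 4; 0.161), DNAJB6 (day 0 replicates 2 to 4 and untreated replicates 1 to 4; 0.170). A further one was PAX5 (day 0 replicates 2 and 3 and untreated replicates 1 to 3; 0.183).

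With the replicate number as a block, the counts were 2785, 6969, 22 and 2663, the overlaps 2315 and 2286, and the called lists 3, 0, 0 and 3. The numbers do not pair the arrays: of 24 pairs of arrays with 1 number, 4 correlated above 0.1 (range -0.387 to 0.712).

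The log2 changes of named genes that changed sign were as follows. With the mean of a gene's probes they were for probiotic against untreated ANXA11 0.85, TLR4 0.57, and for probiotic against day 0 ANXA11 2.25, ANXA6 1.96, METTL2A 1.19. They were for LPS IL1B -0.16, and for untreated against day 0 IL1B 0.20. With quantile normalization they were for probiotic against untreated TLR4 1.05, and for untreated against day 0 CXCR2 -0.23. Scaled to the median they were for probiotic against untreated CD14 0.25, TLR4 1.81, and for probiotic against day 0 IL10 0.33. With cyclic loess they were for probiotic against day 0 IL1B -1.63, and for LPS IL10 0.62. With normexp and quantile normalization they were for probiotic against untreated TLR4 0.21, and for probiotic against day 0 BPI -0.63, CD14 -0.0868, CYC1 -0.00379, F13A1 -0.0863, IL10 0.35, RPL13 -0.21. They were for LPS CD14 0.12, and for untreated against day 0 BUB1 -0.13, CXCR2 -0.47, DNAJB6 -0.89, TLR4 -0.16. With normexp and the 75th percentile they were for probiotic against untreated TLR4 0.33, and for probiotic against day 0 IL10 0.86, TLR4 -0.13. They were for untreated against day 0 BUB1 -0.34, CSF1 -0.0362, CXCR2 -0.37, DNAJB6 -0.54, TLR4 -0.46. Before detrending they were for probiotic against untreated TLR4 0.56, and for probiotic against day 0 BPI -0.59, CD14 -0.72, IL10 0.91, RPL13 -0.46, SLC25A37 -0.34, TLR4 -0.89, TRAT1 -0.12. They were for untreated against day 0 BCL3 -0.84, BUB1 -1.84, CSF1 -1.38, CX3CR1 -0.65, CXCR2 -2.63, DNAJB6 -2.97, FZD7 -0.0817, KIT -0.63, OAS2 -0.44, TLR4 -1.45. Scaled on probes detected everywhere they were for probiotic against day 0 IL1B -0.58, TLR4 -1.03, and for LPS CD14 0.20, IL10 0.22.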

Other observations

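The test of pools that differ in MHC class II genes, like all values from the outer rows of the array before detrending, was chosen after the results were seen, while the test of local signal loss was fixed before its result. Day 0 and LPS replicates 4 are left out of these values, and the genes were chosen after their values were seen. In these rows 3533 genes were tested, and the group means of probiotic and day 0 correlated at 0.956 and those of LPS and probiotic at 0.990 across genes, which are not independent replicates. Between probiotic and day 0, 86 genes passed in limma, 46 up and 40 down. BOLA-DQA5 was at least 88.1-fold higher (adjusted p = 4.35e-09, 4 against 3 arrays), and DAGLA, a lipase that makes an endocannabinoid, at least 6.71-fold (adjusted p = 8.61e-05). FOS rose by 3.09 ± 0.50 and the nuclear receptor NR4A2, an immediate early gene too, was at least 1.99-fold higher (adjusted p = 0.00620 and 0.00866). The other 3 immediate early genes in these rows did not pass (PPP1R15A 0.46, KLF6 0.29 and EGR1 -1.90), and camera did not call the 5 (adjusted p = 0.0718). CPT1A, which brings fatty acids into mitochondria, fell by 2.61 ± 0.33, and APOE, a lipid carrier, fell by 1.98 ± 0.31 (adjusted p = 0.000744 and 0.00593). Camera called the ribosomal proteins down (20 genes, median -0.60, adjusted p = 0.00109), but not with an estimated correlation (adjusted p = 0.981).

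Between LPS and probiotic, 0 genes passed in limma in the outer rows, and 98 had an unadjusted p under 0.05. Camera called the immediate early genes up with LPS (5 genes, median 0.53 against -0.29 for all genes, adjusted p = 7.14e-07, and 0.0294 with an estimated correlation), and all 5 lay above the median of all genes. None passed singly. Over the whole array the list of 15 genes was not called (median -0.42; adjusted p = 0.417, 0.987 with an estimated correlation and 0.154 before detrending). The log2 differences were 1.12 for FOS, 0.66 for NR4A2, 0.53 for PPP1R15A, 0.50 for EGR1 and -0.01 for KLF6.

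BOLA-DQA5 was bright on all probiotic and LPS arrays and dim on all day 0 and untreated arrays. These values rest on 1 spot per array, for 1 of the 2 probes of the gene. A local loss of signal on the day 0 arrays is argued against by 145 neighbouring spots, whose median log2 change was 0.0856. Of the other 8 class II genes in the outer rows none passed; BOLA-DQA1 and BOLA-DQB1 had log2 changes of 1.81 and 1.13 (adjusted p = 0.272 and 0.121), and the other 6 ran from -0.34 to 0.46. Pools that differ in their MHC class II genes are argued against by the labels, on which the day 0 pool holds the probiotic cows, alone or with as many others: this permits a fold of up to 2, and the fold was at least 88.1 in the outer rows and at least 70.3 with all 4 day 0 arrays. A day 0 pool of other cows than the labels give, and a change in expression with the supplement, stay open and untested; the cows' genotypes were not analysed here.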
